A study of Mus musculus with 13 samples.

How the data were processed

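Whole hippocampi of 13 mice on a C57BL/6J background, aged 1 to 2 months and kept on a standard diet, were profiled on 13 arrays, each mouse on an array of its own. The labels give 4 wild-type and 3 Kmt2d+/βGeo mice in experiment 1, which received no injections, and 3 wild-type and 3 Kmt2d+/βGeo mice in experiment 2, which received 3 saline injections a day. All mice are labelled female except wild-type replicate 3 of experiment 1, whose sex is labelled unknown. Total RNA was extracted with RNeasy columns and labelled with biotin after amplification with the Ambion WT Expression kit, per the labels' protocols. The arrays are of the Affymetrix Mouse Gene 1.0 ST design, whose probes are spread along each transcript.

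The deposited table holds log2 intensities, 1 value per probe set and array, made by the authors with RMA in the oligo package, per the submitters' processing notes. RMA corrects background, equalises the distributions of the arrays it is given and combines the probes of a probe set by median polish. The version of oligo, the genome build and whether the 13 arrays were normalised in a single run are not given in the sources used here. The table has 35556 probe sets with values from 2.53 to 14.2. The array medians were 6.75 to 6.90 in experiment 1 and 7.04 to 7.08 in experiment 2. No columns were identical, and the highest correlation between any 2 arrays was 0.998. Pairs of arrays shared many values exactly. A mean of 423.6 probe sets per pair within an experiment, and 263.5 per pair between experiments, held equal values to 4 decimals, against 14.1 and 4.48 per step of 0.0001 among values slightly further apart. Median polish gives such ties when an array's estimated effect is 0, and 4403 probe sets (12.4%) held a tie across the experiments. Ties between experiments at this rate are what a median polish of all 13 arrays together gives, while they do not show whether the background and quantile steps before it were also run together. A standard deviation (SD) near 0 in a group with tied arrays therefore understates the spread between mice.

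Probe sets were named from the platform annotation supplied with the data. It lists 23410 of the 35556 probe sets, 21789 with 1 gene symbol and 1621 with several, and the other 12146 stayed unnamed here and entered only the tests of every probe set. The 19938 genes with a probe set of their own were tested, each represented by the probe set with the highest mean over the 13 arrays, which was a choice between several for 999 genes. No filter on dim probe sets was applied, and no per-sample column was left unused.

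Tests were run on the log2 values with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with statmod 1.5.0 for array weights and blocks. The genotype effect over both experiments and the difference between the experiments came from a model with genotype and experiment as terms. The genotype effect within each experiment, and the difference of these effects, came from a model of the 4 groups, which share an estimate of the spread. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and the threshold was an adjusted p of 0.05. Errors are standard errors (SE) from limma unless an SD is named. The mice are separate animals per the labels, and the number of arrays limits the precision. The injections, the array run and any separate step of normalisation before the median polish differ together between the experiments, so the difference between the experiments describes all of them at once.

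The model, the threshold, the rule for naming genes, 40 gene lists and the other settings to try were fixed before the data were examined. Kmt2d was to be reported first, and then the genes past the threshold. Because fewer passed than the rule allowed for, it added genes with the same sign in both experiments in order of unadjusted p, up to 20. The rule also took the 5 genes of lowest p past the threshold in each experiment, the 6 genes that rose most and the 6 that fell most between the experiments, and up to 4 members of lowest p per list. The lists covered chromatin and metabolic pathways, stress and activity responses, neuronal and glial cell types of the hippocampus, and tissues that border it. Of their 868 distinct members, 785 were measured, and all 40 lists could be tested. Lists were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the 40 lists, with camera at an estimated correlation and fry as alternatives. Single probe sets and list means were also compared by exact permutation of genotype within experiments, which allows 700 regroupings, so that the smallest p is 0.00143 over both experiments, 0.0286 for 3 against 4 mice and 0.1 for 3 against 3. Adjusted over the 40 lists, a list at these smallest p-values cannot pass alone, so this test could hardly pass a list.

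These other settings were every probe set in place of 1 per gene, the lowest 30% or 50% of genes by mean left out, eBayes with trend and robust settings, array weights, array medians made equal, quantile normalisation over all arrays or within each experiment, a looser adjusted p of 0.1, experiment as a random block or not modelled, each experiment alone, the replicate number as a block, and each array left out in turn. After the data were seen, 3 alternatives were added: leaving out together the arrays that stood apart (wild-type replicates 2 and 3 of experiment 1 and heterozygous replicate 3 of experiment 2), means of the choroid plexus, striatum and myelin lists as covariates, and the exact permutation of list means. The named genes were then also run under each setting used for the counts of genes. The steps were tested on simulated data with 200 of 19938 genes changed. At a true change of 0.6 on the log2 scale, 98% of the changed genes were recovered for the genotype effect over both experiments, 88% within experiment 1, 72% within experiment 2 and 48% for the difference of the effects. At a true change of 0.3 these shares were 54%, 10%, 4% and 2%. The simulated genes varied independently, and 200 changed genes make the adjusted threshold easier to pass. The shares therefore do not give what would be recovered on the real arrays. With no list changed, 0 of 40 lists passed with camera on simulated genes, which vary independently, unlike those of the real arrays.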

Results

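Gene expression was measured in whole hippocampus of 7 wild-type and 6 Kmt2d+/βGeo mice on 13 arrays. Kmt2d encodes a methyltransferase of histone H3 lysine 4, and the βGeo allele is a gene trap. Heterozygous loss of KMT2D in humans causes Kabuki syndrome, a disorder with intellectual disability. The arrays came from 2 experiments, the first with 4 wild-type and 3 heterozygous mice and the second with 3 of each. The first component of the 13 arrays held 83.6% of the variance and separated the experiments. Correlations between arrays over the 19938 genes were 0.991 to 0.998 within experiment 1, 0.985 to 0.994 within experiment 2 and 0.936 to 0.959 between them.

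Kmt2d has 2 probe sets, both on chromosome 15, which went different ways. Probe set 10432294 was lower in heterozygous mice of both experiments, at 7.33 ± 0.15 (SD, n = 3) against 7.88 ± 0.01 (SD, n = 4) log2 units in experiment 1, exact permutation p = 0.0286, the smallest 3 against 4 mice allow. In experiment 2 it was 8.02 ± 0.15 against 8.53 ± 0.22 (SD, n = 3 each), exact permutation p = 0.1, the smallest 3 against 3 allow. Over both experiments the difference was -0.53 ± 0.08, or 69.3% of the wild-type level, with every heterozygous mouse below every wild-type mouse of its experiment (exact permutation p = 0.00143, the smallest possible; limma adjusted p over all probe sets 0.427). Probe set 10432298, which has the higher signal and so stood for the gene, was 9.91 ± 0.06 against 9.82 ± 0.01 in experiment 1 (SD, n = 3 and 4; exact permutation p = 0.0286) and 9.69 ± 0.17 against 9.63 ± 0.18 in experiment 2 (SD, n = 3 each; exact permutation p = 0.8). Its difference over both experiments was 0.07 ± 0.07 (limma adjusted p = 0.936). The mean of both probe sets gave -0.23, the opposite sign, with adjusted p = 0.388, within a range of 0.388 to 1 over the alternatives. Which part of the transcript each probe set covers, and on which side of the gene trap, is not given in the sources used here, so neither is a full check of the genotype labels. The SDs of 0.01 in wild-type mice of experiment 1 come from arrays with tied values and understate the spread.

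**Figure D1:**
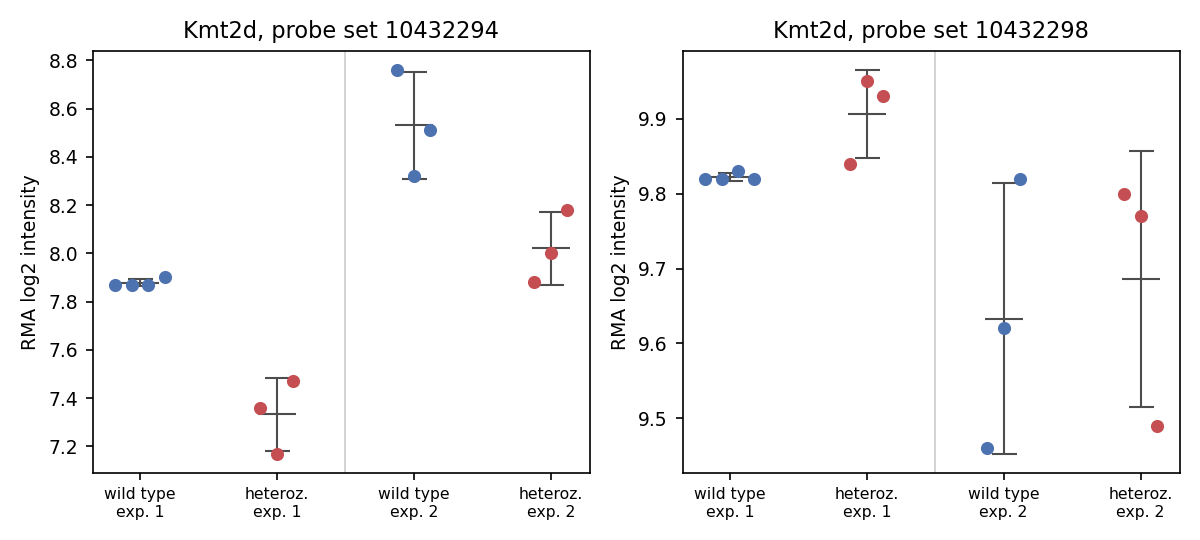
RMA log2 intensity of the 2 Kmt2d probe sets on each of the 13 arrays, by genotype and experiment; points are mice, bars the mean ± SD. Heterozygous mice lie below wild-type mice of their experiment for probe set 10432294 and not for 10432298.

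The sex-linked genes were read on each array because 1 mouse was of unknown sex. Wild-type replicate 3 of experiment 1, the mouse of unknown sex, had Xist, the RNA that coats the inactive X chromosome, at 4.81 log2 units, against 10.70 to 11.48 on the other arrays. Its Y-linked genes were high, Eif2s3y at 8.14 against 3.56 to 3.67, Kdm5d at 7.55 against 4.39 to 4.83 and Uty at 8.83 against 3.69 to 4.16. The array labelled unknown thus carried a male pattern, and all arrays labelled female a female pattern. The list of Xist and Y-linked genes had a mean genotype difference of -0.19 (camera adjusted p = 0.59).

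The main comparison asked which genes differ between Kmt2d+/βGeo and wild-type hippocampus over both experiments. The genes of lowest p were mostly lower in heterozygous mice: of the 20 named by rule, 17 were lower and 3 higher. Pld5, of the phospholipase D family, differed by -0.87 ± 0.14 (1.83-fold lower, 6 heterozygous and 7 wild-type mice). The calcium-activated chloride channel Ano2 differed by -0.77 ± 0.12 (1.70-fold) and the cortexin Ctxn3 by -0.55 ± 0.10 (1.47-fold). The developmental transcription factor Zic1 and the glucagon-like peptide receptor Glp1r each differed by -1.03, with errors of 0.19 and 0.23 and folds of 2.04 for both. The genes with higher values were Kcnc2, a potassium channel subunit of fast-spiking neurons, at 0.35 ± 0.07, Trhde, which degrades thyrotropin-releasing hormone, at 0.29 ± 0.06, and the formin Fmnl1 at 0.24 ± 0.05.

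None of the 20 passed the threshold. With limma, 0 of 19938 genes had an adjusted p under 0.05, the smallest being 0.121, for Ano2 and Pld5, and 1046 had an unadjusted p under 0.05 where 996.9 are expected by chance. With every probe set tested the count was also 0. Lower values outside the threshold were further found for Ecel1, a metallopeptidase of the neprilysin family (-0.81 ± 0.17), Slc10a4, a vesicular protein of cholinergic neurons (-0.76 ± 0.17), and Cacna2d2, a calcium channel subunit (-0.55 ± 0.11). Postn, a secreted matrix protein, differed by -0.55 ± 0.12, the adhesion receptor Adgrd1 by -0.47 ± 0.10, the postsynaptic protein Lzts1 by -0.41 ± 0.09 and the transcription factor Zic4 by -0.38 ± 0.08. The second probe set of Zic4 differed by -0.05. The remaining lower genes were Tmem91 (-0.43), Tbc1d2b (-0.34), Zfp521 (-0.33), the thrombin inhibitor Serpind1 (-0.33) and the collagen chain Col6a3 (-0.32). The genotypes did not overlap for 18 of the 20 genes in experiment 1 and 13 in experiment 2, which follows largely from naming genes by low p and common sign on these arrays and is no further test. Over all genes these shares were 7.22% and 9.48%, where chance gives 5.71% and 10%. With array weights 21 genes passed, 3 higher and 18 lower, among them Ctxn3, Pld5, Ano2, Postn and Glp1r. Leaving out 1 array let Glp1r pass without wild-type replicate 2 of experiment 1 (adjusted p = 0.00813, range over its alternatives 0.00813 to 1), Pld5 and Adgrd1 without wild-type replicate 1 of experiment 2 (both adjusted p = 0.0241, ranges 0.00465 to 1 and 0.0167 to 1) and Lzts1 without heterozygous replicate 1 of experiment 2 (adjusted p = 0.0464, range 0.0464 to 1).

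**Figure D2:**
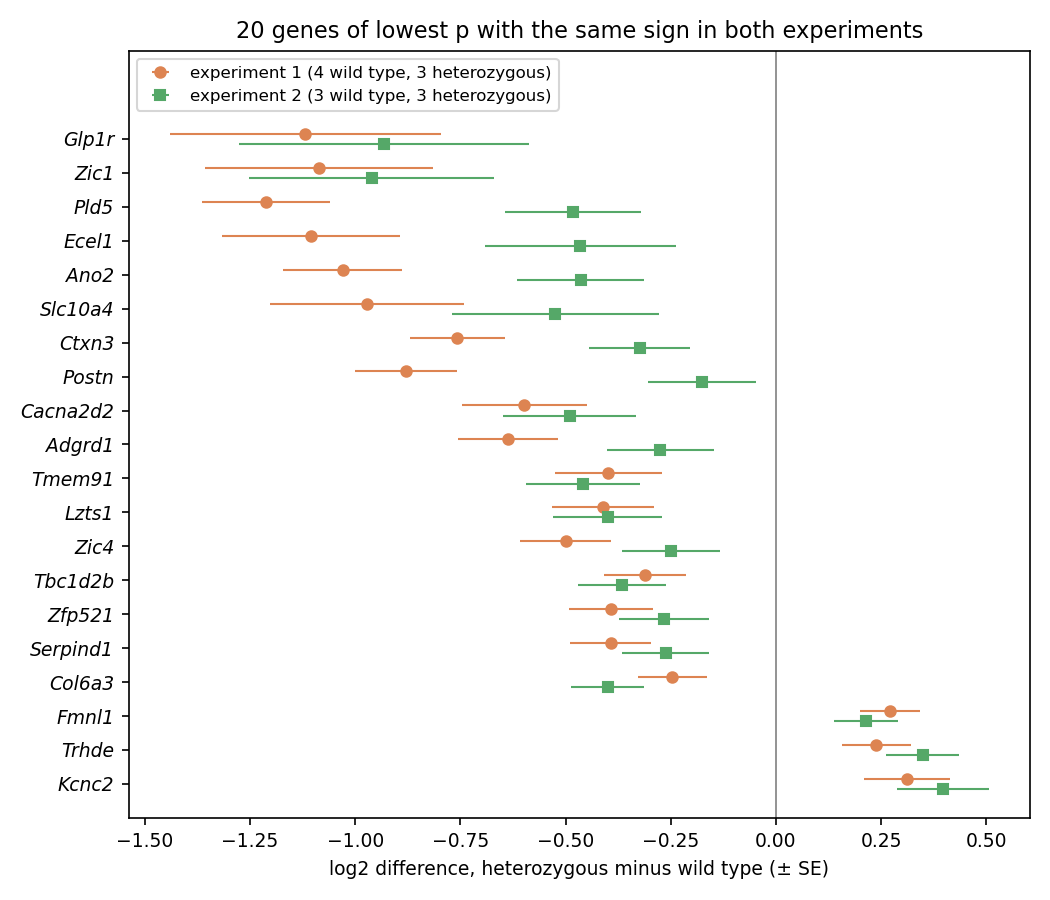
Log2 difference, heterozygous minus wild type, of the 20 named genes in experiment 1 (4 wild-type and 3 heterozygous mice) and experiment 2 (3 and 3); bars are SE from limma. The rule for naming them required the same sign in both experiments, 17 lower and 3 higher.

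By gene list, markers of dentate granule cells, the principal neurons of the dentate gyrus, were higher in heterozygous mice, with a mean difference of 0.15 and 19 of 20 members above 0. Cholesterol synthesis was higher by a mean of 0.06, with 17 of 20 members above 0. Markers of tissues that border the hippocampus had negative means: -0.31 for choroid plexus (22 of 23 members below 0), -0.36 for striatum (18 of 18), -0.15 for meningeal fibroblasts and collagens (21 of 22) and -0.11 for ependymal cells, which line the ventricles (15 of 18). The experiments went opposite ways for the choroid plexus, at -0.86 in experiment 1 and 0.32 in experiment 2, and for ependymal cells, at -0.34 and 0.15. The choroid plexus sign in experiment 2 rested on wild-type replicate 3, whose list mean was -1.14. The other wild-type mice were at -0.50 and 0.26, and heterozygous mice at -0.61 to 0.37. The striatum and dentate means were -0.62 and 0.28 in experiment 1 and -0.07 and -0.003 in experiment 2. Smaller negative means were found for the circadian clock (-0.065, 14 of 18 below 0), fatty acid oxidation (-0.05, 18 of 23), glucocorticoid-induced genes (-0.05, 13 of 17) and inhibitory neurons (-0.06, 13 of 20).

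These 10 lists passed with camera. Adjusted p was 3.48e-05 for dentate granule cells and for meningeal fibroblasts, 3.95e-05 for choroid plexus and for striatum, 0.000932 for ependymal cells, 0.0181 for cholesterol synthesis and for the circadian clock, 0.0368 for fatty acid oxidation, 0.0394 for glucocorticoid-induced genes and 0.0396 for inhibitory neurons. None of the 10 held otherwise: adjusted p = 0.535 with an estimated correlation for the circadian clock and adjusted p = 0.701 with an estimated correlation for each of the other 9. The smallest adjusted p was 0.438 with fry and 0.767 by exact permutation of the list means, where the circadian clock had an unadjusted exact permutation p = 0.0329. No member of any list passed over all genes. Adjusted over the list alone, 1 dentate member (Trpc6, a cation channel, 0.34 ± 0.09), 1 cholesterol enzyme (Idi1, 0.31 ± 0.08) and 1 meningeal gene (Col6a3, -0.32 ± 0.06) passed, and none in the other 7 lists. Other members of low p were Dgkh (0.18) among dentate markers and Hmgcs1 (0.18) among cholesterol enzymes. The matrix proteins Bgn (-0.33) and Pcolce (-0.55) led the meningeal list with Col6a3, and Isl1 (-0.47 ± 0.14) was the only striatum member with an unadjusted p under 0.05, the dopamine receptor gene Drd2 being at -0.75 ± 0.43 (limma unadjusted p = 0.102). Cox8b (-0.74) and Clic6 (-0.71) led the choroid plexus list and Cfap126 (-0.24), a protein of cilia, the ependymal list. Among clock genes, Nr1d1 (-0.23), Per1 (-0.17) and Cry1 (-0.17) were lower and Nfil3 (0.29) was higher. Etfa (-0.14) and the carnitine transferase Cpt1a (-0.17) were lower among fatty acid oxidation genes, Nfkbia (-0.25) among glucocorticoid-induced genes, and the GABA-synthesising enzymes Gad2 (-0.23 ± 0.07) and Gad1 (-0.14 ± 0.05) among inhibitory neuron markers, where the neuropeptide gene Npy was at 0.16.

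Single arrays carried part of these lists. The striatum list mean was 2.2 log2 units above the mean of all arrays in wild-type replicate 2 of experiment 1, against -0.47 to 0.04 on the other arrays, and the list's difference was -0.07 without that array (adjusted p = 0.115, range over its alternatives 6.9e-08 to 0.807). With 3 arrays that stood apart left out (wild-type replicates 2 and 3 of experiment 1, heterozygous replicate 3 of experiment 2), 4 of the 10 lists passed: dentate granule cells (0.10), meningeal fibroblasts (-0.25), choroid plexus (-0.53) and ependymal cells (-0.12). Without heterozygous replicate 3 of experiment 1 alone 5 lists passed, and without wild-type replicate 3 of experiment 1 alone 6.

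The other 30 lists did not pass. The mean difference was 0.04 for the H3K4 methylation machinery (adjusted p = 0.135) and 0.005 for 49 genes flanking Kmt2d on chromosome 15 (0.769). Among metabolic lists it was 0.02 for ketone bodies (0.704), -0.01 for oxidative phosphorylation (0.687), -0.004 for glycolysis and the tricarboxylic acid cycle (0.769) and 0.02 for NAD metabolism (0.759), where the nicotinamide riboside kinase Nmrk1 (0.35 ± 0.09) passed adjusted over the list alone. Among stress and activity lists it was -0.01 for hypoxia (0.687), 0.04 for the integrated stress response (0.158), -0.02 for heat shock (0.687), -0.01 for immediate early genes (0.687), 0.05 for interferon (0.13) and -0.02 for class I histocompatibility genes (0.698). Dividing cells had 0.04 (0.112) and neural progenitors -0.04 (0.44), with Eomes, a marker of intermediate progenitors, at -0.37 ± 0.10 and past the threshold adjusted over the list alone. Among neuronal lists the mean was 0.01 for CA1 (0.704), 0.01 for CA3 and CA2 (0.342) and 0.04 for glutamate receptors (0.11; exact permutation p = 0.0443, 0.767 adjusted over the lists). Among glia and vessels it was 0.01 for astrocytes (0.62), -0.05 for myelin (0.196), 0.01 for oligodendrocyte precursors (0.793), -0.03 for microglia (0.116) and -0.02 for endothelium (0.59). In the microglia list Fcrls (0.40 ± 0.11) was higher and Ctss (-0.26 ± 0.07) lower when adjusted over the list alone. Thalamus markers had -0.07 (0.631) and cortex markers -0.09 (0.116), with Zic1 lower and Scube1 (0.30 ± 0.07) higher adjusted over each list alone. Hypothalamic and pituitary hormones had -0.02 (0.687), blood cells -0.02 (0.687), ribosomal proteins -0.02 (0.478), histones -0.04 (0.687) and extracellular matrix 0.01 (0.687). Single arrays decided the call of 8 of these lists. Myelin passed as lower without wild-type replicate 1 (adjusted p = 1.12e-06), heterozygous replicate 3 (0.00625) or heterozygous replicate 2 (0.0173) of experiment 2, and its mean was -0.27 in experiment 1 and 0.20 in experiment 2. Cortex (0.0218) and thalamus (0.0149) passed as lower without heterozygous replicate 2 and microglia (0.0273) without heterozygous replicate 1 of experiment 1. Of experiment 2, leaving out heterozygous replicate 1 let dividing cells (0.0455) and the stress response (0.0244) pass as higher, wild-type replicate 1 dividing cells (0.0382), wild-type replicate 3 glutamate receptors (0.0295) and heterozygous replicate 3 the H3K4 machinery (0.0385). Median, mean and test differed in sign for 5 lists: the camera direction was up with a median of -0.003 for the flanking genes, -0.007 for ketone bodies and -0.006 for extracellular matrix, up with a median of 0.05 and a negative mean for hormones, and down with a median of 0.01 for thalamus.

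**Figure D3:**
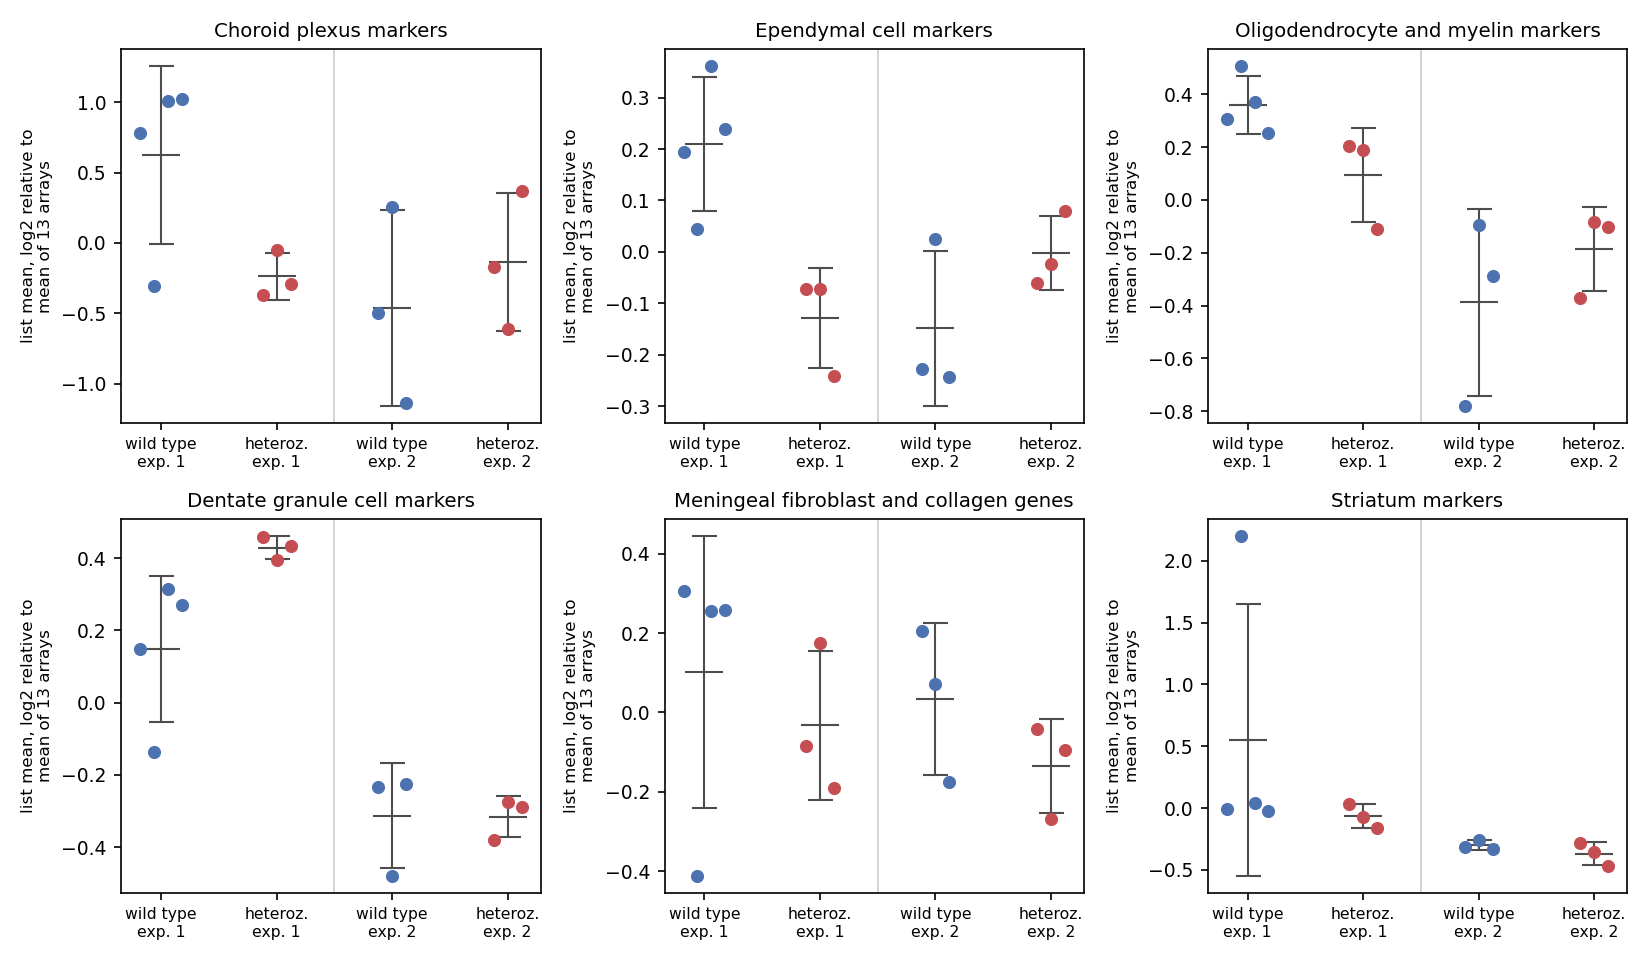
Mean of 6 gene lists on each of the 13 arrays, in log2 units relative to the mean of all arrays, by genotype and experiment; points are mice, bars the mean ± SD. The striatum mean of 2.2 belongs to a single wild-type array of experiment 1.

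Within experiment 1, where mice had no injections, 4 genes fell in heterozygous mice and none rose with arrays weighted equally. Pld5 fell by 1.21 ± 0.15 on the log2 scale (2.32-fold; limma adjusted p = 0.0161), from 8.57 ± 0.25 (SD, n = 4) to 7.36 ± 0.19 (SD, n = 3). Ano2 changed by -1.03 ± 0.14 (2.04-fold; limma adjusted p = 0.0163), Postn by -0.88 ± 0.12 (1.84-fold; limma adjusted p = 0.0163) and Ctxn3 by -0.76 ± 0.11 (1.69-fold; limma adjusted p = 0.0305). For each of the 4 genes all 3 heterozygous mice lay below all 4 wild-type mice. Markers of the choroid plexus were lower, with a mean of -0.86 and 23 of 23 members below 0, as were those of ependymal cells (-0.34, 18 of 18), striatum (-0.62, 18 of 18) and myelin (-0.27, 19 of 20), while dentate granule cell markers were higher (0.28, 19 of 20 above 0). The choroid plexus list mean of wild-type replicate 2, at -0.31, lay within the heterozygous range of -0.37 to -0.05.

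For experiment 1, 698 genes had an unadjusted p under 0.05, fewer than the 996.9 expected by chance. That count uses the spread shared with experiment 2. With only the arrays of experiment 1 it was 1282, more than the number expected. The number of calls depended on single arrays: 0 genes passed without wild-type replicate 3, heterozygous replicate 2 or heterozygous replicate 3, 2 without heterozygous replicate 1 and 48 without wild-type replicate 2, and 0 passed when every probe set was tested or the dimmer 50% of genes was left out. With array weights 163 passed, 15 higher and 148 lower. Adjusted p with single arrays left out ranged from 0.00487 to 0.214 for Pld5, 0.0109 to 0.214 for Ano2, 0.0044 to 0.214 for Postn and 0.00802 to 0.232 for Ctxn3. The differences moved less, from -1.32 to -1.10 for Pld5, -1.17 to -0.92 for Ano2, -0.94 to -0.82 for Postn and -0.83 to -0.69 for Ctxn3. Among the lists, 10 passed with camera. Adjusted p was 8.55e-30 for choroid plexus (adjusted p = 0.241 with an estimated correlation), 9.5e-24 for ependymal cells (adjusted p = 0.082 with an estimated correlation), 1.23e-13 for dentate granule cells (adjusted p = 0.21 with an estimated correlation), 1.23e-13 for myelin (adjusted p = 0.408 with an estimated correlation) and 3.34e-11 for striatum (adjusted p = 0.556 with an estimated correlation). No member passed over all genes. Adjusted over the list alone, 11 choroid plexus genes were lower, among them Clic6 (-1.34 ± 0.32), Steap1 (-0.67) and the lipid transporter Abca4 (-1.15), and 9 ependymal genes, among them the cilia genes Sntn (-0.65 ± 0.12), Dnah11 (-0.48) and Rsph4a (-0.66). By the same measure 5 dentate genes were higher, among them Lct (0.66 ± 0.16), Trpc6 (0.47) and Stxbp6 (0.41), 1 myelin gene was lower, Aspa (-0.64 ± 0.16), an enzyme of oligodendrocytes, and 1 striatum gene, Isl1 (-0.68). Meningeal fibroblasts had a mean of -0.13 (adjusted p = 8e-04; adjusted p = 0.704 with an estimated correlation), dividing cells 0.08 (0.00824; adjusted p = 0.431 with an estimated correlation), cholesterol synthesis 0.08 (0.00982; adjusted p = 0.556 with an estimated correlation), glucocorticoid-induced genes -0.07 (0.0118; adjusted p = 0.701 with an estimated correlation) and the circadian clock -0.07 (0.0252; adjusted p = 0.264 with an estimated correlation), with no member past the threshold adjusted over the list alone. The smallest adjusted p was 0.161 with fry and 0.457 by exact permutation, which could hardly pass a list, its smallest p being 0.0286 before adjustment. With the 3 arrays that stood apart left out, 6 lists passed, and the striatum list had a mean of -0.05 (adjusted p = 0.454).

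Within experiment 2, where mice had saline injections, the marker lists of the ventricles and of myelin had the opposite sign. Choroid plexus markers were higher in heterozygous mice by a mean of 0.32, with 21 of 23 members above 0, ependymal markers by 0.15 (12 of 18) and myelin markers by 0.20 (18 of 20), and meningeal markers were lower by a mean of -0.17 (17 of 22 below 0). The choroid plexus and myelin differences each rested on 1 wild-type array. Replicate 3 had a choroid plexus mean of -1.14, against -0.50 and 0.26 in the other wild-type and -0.61 to 0.37 in heterozygous mice. Replicate 1 had a myelin mean of -0.78, against -0.10 and -0.29 in the other wild-type and -0.37 to -0.08 in heterozygous mice. No choroid plexus member had an unadjusted p under 0.05, the lowest being that of Ttr, the transthyretin gene (1.12 ± 0.59; limma unadjusted p = 0.0767). Members of low p in the other lists were the ependymal genes Mlf1 (0.37) and Tmem212 (0.35), the myelin genes Tspan2 (0.48 ± 0.15) and Ugt8a (0.45), and Col6a3 (-0.40 ± 0.09), which alone passed adjusted over its list alone. The pituitary hormone genes Prl and Gh, chosen after their values were seen, were at -2.08 ± 0.70 (limma adjusted p = 0.382) and -0.75.

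With limma 0 genes passed in experiment 2, the smallest adjusted p being 0.162, and 2042 had an unadjusted p under 0.05 where 996.9 are expected. That count uses the spread shared with experiment 1. With only the arrays of experiment 2 it was 1006, close to the number expected. Without heterozygous replicate 1 of experiment 2, 91 genes passed. Camera adjusted p was 0.00449 for myelin and 0.0224 for each of the other 3 lists, and adjusted p = 0.969 with an estimated correlation for all 4. The smallest adjusted p was 0.863 with fry. None of the 4 passed without wild-type replicate 1, 2 passed without wild-type replicate 3, and 1 without each heterozygous replicate of this experiment. With the 3 arrays that stood apart left out only meningeal fibroblasts passed (-0.19, adjusted p = 0.000505), and the choroid plexus mean was 0.07 (adjusted p = 0.904).

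The difference of the genotype effect between the experiments was tested directly. The effect on choroid plexus markers was higher in experiment 2 by 1.187 (23 of 23 members), on ependymal markers by 0.486 (17 of 18), on striatum markers by 0.552 (17 of 18) and on myelin markers by 0.468 (20 of 20), and on dentate granule cell markers it was lower, at -0.282 (16 of 20). Members of low p were Otx2, a transcription factor of the choroid plexus (1.69 ± 0.52), Sntn (0.96 ± 0.18), Ermn (0.90 ± 0.27) and Lct (-0.92 ± 0.24). With limma 0 genes passed, the smallest adjusted p being 0.554, and 1301 had an unadjusted p under 0.05. These 5 lists passed with camera: choroid plexus at adjusted p = 6.58e-18 (adjusted p = 0.839 with an estimated correlation), ependymal cells at 1.94e-14 (adjusted p = 0.356 with an estimated correlation), myelin at 4.7e-12 (adjusted p = 0.839 with an estimated correlation), dentate granule cells at 0.000235 and striatum at 0.00181 (both adjusted p = 0.964 with an estimated correlation). Adjusted over the list alone, 6 ependymal, 3 myelin and 1 choroid plexus genes were higher and 4 dentate genes lower. By exact permutation p was 0.00857 for ependymal cells, 0.0571 for myelin, 0.0786 for choroid plexus, 0.101 for dentate granule cells and 0.729 for striatum, and the smallest adjusted p over the lists was 0.343. Without the 3 arrays that stood apart 4 of the lists passed, and striatum was at 0.03 (adjusted p = 0.911).

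Across all genes the genotype effects of the 2 experiments were compared with each other. Among 55 genes at an unadjusted p under 0.05 with the same sign in both experiments were the lipoprotein lipase gene Lpl (0.34 and 0.66), the oxysterol hydroxylase gene Cyp7b1 (0.39 and 0.39), the prostaglandin D synthase gene Ptgds (-0.47 and -0.47) and the synaptic vesicle gene Sv2c (-0.46 and -0.47), chosen after their values were seen. Independent effects would give 36.1 such genes, and 100 regroupings of genotype within experiments gave a median of 16 and up to 153, with 15 of the 100 reaching as many. In the opposite sense 35 genes had a p under 0.05 in both. Over all genes the log2 differences had Pearson r = -0.0258 and Spearman rho = -0.0297, and 48.2% of genes had the same sign. Regroupings gave r from -0.221 to 0.237, 65 of the 100 as far from 0 as the observed value. Genes are not independent replicates, so no p over genes is given.

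Between the experiments, most ribosomal protein genes rose (21 of 25) and most glutamate receptor and scaffold genes fell (22 of 27) in experiment 2, each list past the threshold with camera and at adjusted p = 0.105 with an estimated correlation. Among the genes that moved most, Ndufa1, a subunit of respiratory complex I, rose by 4.41 ± 0.09 on the log2 scale (21.2-fold; 6 mice against 7), the copper chaperone Cox17 by 3.88 ± 0.08 (14.8-fold), the ribosomal protein gene Rps3a1 by 3.31 ± 0.08 and the mitochondrial import gene Tomm7 by 3.28 ± 0.06. Small non-coding RNAs went both ways: the small nucleolar RNA Snord42a rose by 4.48 ± 0.17 and the Y RNA Rny1 by 3.25 ± 0.15, whereas Snord57 changed by -5.03 ± 0.13 (32.8-fold lower), Snord82 by -4.62 ± 0.13, Snora52 by -4.16 ± 0.10, Snord73b by -3.76 ± 0.17 and Snora16a by -3.52 ± 0.20. The zinc-finger gene Zfp931 changed by -3.51 ± 0.14. The limma adjusted p was 1.67e-10 for Snora16a and smaller for the other 11 genes. All 12 kept their direction with array medians made equal and with quantile normalisation.

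Of 19938 genes, 15385 (77.2%) passed with limma, 8331 higher and 7054 lower in experiment 2, 2367 of them by more than 1 log2 unit. The split depended on scaling and on dim genes: 54.2% of the calls were higher as deposited, 28.3% with array medians made equal and 41.1% with quantile normalisation over all arrays, while 4224 were higher and 6817 lower without the lowest 30% of genes by mean, and 2140 and 5880 without the lowest 50%. The median over all genes was 0.07 as deposited, -0.17 with equal medians and -0.05 with quantile normalisation, and list values are to be read relative to it. It does not allow for signal level, as the arrays of experiment 2 had a narrower range. Their lower quartiles were 5.50 to 5.55 against 5.10 to 5.29 in experiment 1, and their upper quartiles 8.59 to 8.66 against 8.80 to 8.87. A list's value as deposited therefore also depends on how bright its genes are. Of the ribosomal protein genes 21 of 25 rose and 2 fell (median 0.81; camera adjusted p = 5.18e-06; adjusted p = 0.105 with an estimated correlation), led by Rps14 (2.11 ± 0.06) and Rpl8 (1.90 ± 0.06). Of the glutamate receptor and scaffold genes 22 of 27 fell and 1 rose (median -0.56; adjusted p = 4.06e-05; adjusted p = 0.105 with an estimated correlation), led by the scaffold gene Dlg3 (-1.61 ± 0.06) and the receptor gene Grm5 (-1.22 ± 0.05). Medians of both lists kept their sign under all 3 scalings, at 0.56 and -0.81 with equal medians and 0.78 and -0.42 with quantile normalisation.

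In all, 16 lists passed with camera, 3 higher and 13 lower. The other two higher lists were hormones, with 14 of 17 genes rising and a median of 0.34 (adjusted p = 0.0194; adjusted p = 0.447 with an estimated correlation), and blood cells, with 7 of 8 (adjusted p = 0.0326; adjusted p = 0.285 with an estimated correlation). With quantile normalisation the medians of these lists were 0.09 and 0.19, with 7 of the 17 hormone genes below 0. Glycolysis had 20 of 28 genes falling and 2 rising (adjusted p = 0.00114; adjusted p = 0.315 with an estimated correlation), led by Pfkl (-1.67 ± 0.07). Among glial and vascular lists, 14 of 20 astrocyte genes fell, led by the water channel Aqp4 (-1.68 ± 0.06), 14 of 20 myelin genes, among them Mbp, the myelin basic protein gene (-1.03 ± 0.09), and 15 of 21 endothelial genes, led by Emcn (-2.29 ± 0.08). Their adjusted p was 0.0144, 0.0221 and 0.0212 (adjusted p = 0.485, 0.618 and 0.485 with an estimated correlation). Among neuronal lists, 14 of 20 dentate genes fell, led by Ahcyl2 (-1.37 ± 0.09), 9 of 13 CA1 genes, led by Nrip3 (-2.11 ± 0.11), and 11 of 19 CA3 and CA2 genes, led by Spock1 (-2.31 ± 0.06). Their adjusted p was 0.00721, 0.0194 and 0.0354 (adjusted p = 0.485, 0.315 and 0.315 with an estimated correlation). Of the clock genes 12 of 18 fell, led by Bhlhe41 (-2.92 ± 0.12), and of the glucocorticoid-induced genes 11 of 17, among them Klf9 (-2.35 ± 0.11), both at adjusted p = 0.0186 (adjusted p = 0.181 and 0.485 with an estimated correlation). Hypoxia genes (16 of 24 fell, 4 rose), stress response genes (15 of 24 fell, 5 rose) and extracellular matrix genes (13 of 23 fell, 3 rose) had adjusted p of 0.0212, 0.0212 and 0.031 (adjusted p = 0.315, 0.485 and 0.315 with an estimated correlation). Counts adjusted over the list alone were the same for these 16 lists except for CA3 and CA2, where 10 genes fell. The medians of the 13 lower lists stayed below 0 under all 3 scalings, though 6 of the 20 dentate genes were above 0 with quantile normalisation. Only 3 lists passed with quantile normalisation, ribosomal proteins and oxidative phosphorylation higher and glutamate receptors lower. Without the lowest 50% of genes by mean 3 passed, ribosomal proteins, oxidative phosphorylation and interferon, all higher, so that none of the 13 lower lists, glutamate receptors among them, kept its call, and 34 passed with fry.

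**Figure D4:**
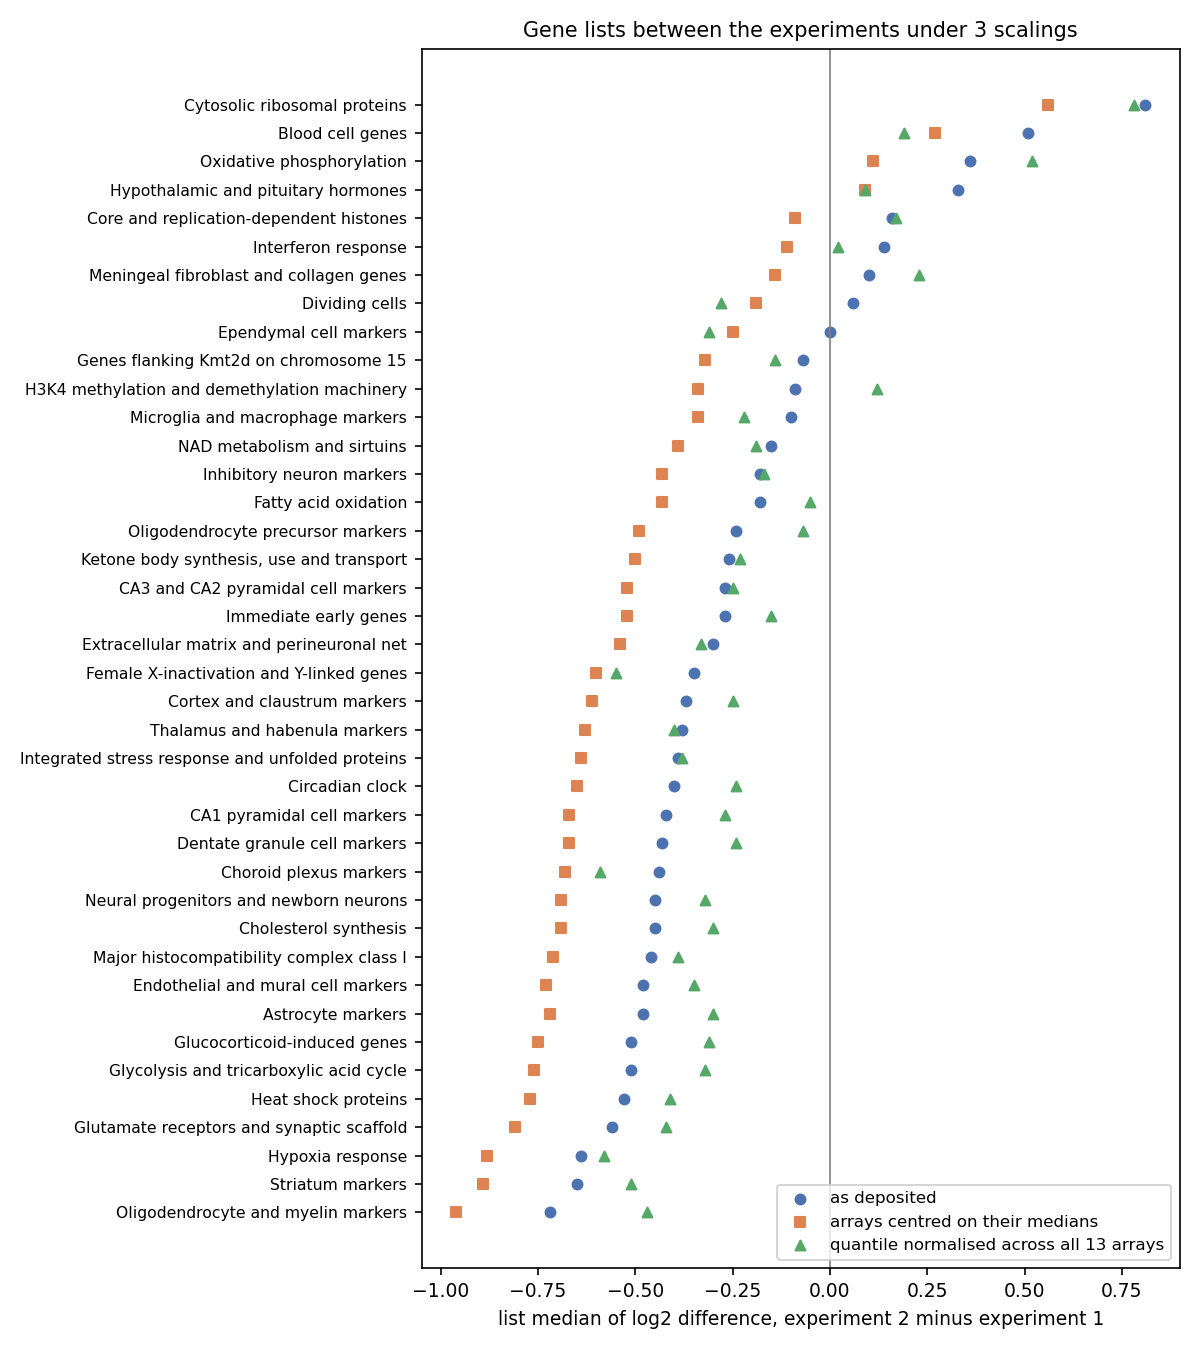
Median log2 difference, experiment 2 minus experiment 1, of the members of each of 40 gene lists under 3 scalings of the arrays. Ribosomal proteins lie highest under every scaling, at 0.81, 0.56 and 0.78, and most lists lie below 0.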

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

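The tests for a mislabelled genotype and for a genotype effect shared by the experiments, the choice of arrays to leave out, and the removal of Calml4 from both lists, came after the results were seen. The prediction for uneven carry-over was written before its test was run, but for a pattern already seen in the results. Choroid plexus markers, which mark the secretory tissue of the ventricles, were lower in heterozygous mice of experiment 1 and higher in those of experiment 2, a difference of the effects of 1.187, and ependymal markers differed likewise, by 0.486; Ttr, known as an abundant transcript of the choroid plexus, was at 13.25 and 12.82 log2 units in wild-type and heterozygous mice of experiment 1 and 11.77 and 12.89 in those of experiment 2. By array, relative to the mean of all arrays, the choroid plexus list lay at 0.78, -0.31, 1.01 and 1.02 in wild-type and -0.37, -0.05 and -0.29 in heterozygous mice of experiment 1, and at -0.50, 0.26 and -1.14 against -0.17, -0.61 and 0.37 in experiment 2. A mislabelled genotype is argued against, though not excluded. The Kmt2d probe set that is lower in heterozygous mice placed 0 arrays on the wrong side of the other genotype. Its difference over both experiments was -0.53 ± 0.08 (limma unadjusted p = 1.2e-05, the lowest of any probe set). However, it was picked for its direction after both probe sets were seen. The other probe set was higher in heterozygous mice of experiment 1 (0.09 ± 0.10, limma unadjusted p = 0.37) and overlapped between genotypes in experiment 2. Uneven carry-over of the ventricular lining at dissection may account for the pattern. With the group means removed, the choroid plexus and ependymal means, without Calml4, which both lists hold, correlated over the 13 arrays. Pearson r was 0.700 (permutation p = 0.00773, adjusted over 2 relations 0.0155) and Spearman rho 0.687 (permutation p = 0.0119, adjusted 0.0238). The value of r was 0.49 without the 2 arrays farthest from the median, 0.673 within experiment 1 (n = 7) and 0.767 within experiment 2 (n = 6). These permutations exchanged residuals freely although removed group means tie them, so their p-values are too small. The same genotype effect in both experiments stays open for the choroid plexus (exact permutation p of the difference 0.0786); for ependymal markers that p was 0.00857, or 0.343 adjusted over the 40 lists, and an effect of genotype that depends on the injections was not tested apart from the array run.

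The other differences of the genotype effect between experiments past the camera threshold were 0.468 for myelin, -0.282 for dentate granule cells and 0.552 for striatum (adjusted p = 0.839, 0.964 and 0.964 with an estimated correlation), the last of which was 0.03 without the 3 arrays that stood apart. Among the 4 wild-type mice of experiment 1, 7 of 74 groups of values tested had a mouse set apart from the others, where 3.7 are expected by chance, as about 1 in 20 would be. For 4 of the 7 it was replicate 2, with Kcnc2 at 9.89 against 10.19 to 10.25, Glp1r at 8.12 against 9.63 to 9.91, the meningeal list mean at -0.41 against 0.26 to 0.31 and the striatum list mean at 2.2 against -0.02 to 0.04. Replicate 3 was apart for the list of Xist and Y-linked genes, whose mean was 1.36, through its male pattern, and for Kmt2d probe set 10432298, at 9.83 against 9.82. Replicate 4 was apart for Kmt2d probe set 10432294, at 7.9 against 7.87. Both Kmt2d values stand out against tied arrays, whose spread is understated.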

How the results depend on the processing

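The alternatives that leave out 3 arrays together, use list means as covariates or permute list means, and part of the settings for single genes, were chosen after the data were seen. Genes for both experiments: 0 of 19938 passed with limma (1046 at an unadjusted p under 0.05), against 21 with array weights (3 higher, 18 lower), 4 with list means as covariates (Glp1r, Zic1 and Pld5 lower, Ppid higher) and 0 to 2 with 1 array left out (2 without wild-type replicate 1 of experiment 2, 1 without wild-type replicate 2 of experiment 1 or heterozygous replicate 1 of experiment 2). For experiment 1, 4 became 0 with every probe set or the lowest 50% of genes left out, 163 with array weights (15 higher), 2 with quantile normalisation over all arrays (Pld5, Postn), 2 with only its own arrays (Vat1l, Postn), and 0 to 48 with 1 array left out (48 without wild-type replicate 2, 2 without heterozygous replicate 1, 0 without wild-type replicate 3 or heterozygous replicate 2 or 3). For experiment 2, 0 (2042 at an unadjusted p under 0.05) became 2 with quantile normalisation (Mysm1 higher, 1700028J19Rik lower) and 0 to 91 with 1 array left out (91 without its heterozygous replicate 1). The difference of the effects stayed at 0 with limma under all 24 alternatives (1301 at an unadjusted p under 0.05 in the model as reported). The 15385 of 19938 genes between experiments became 26086 of 35556 with every probe set and 14931 to 15594 with 1 array left out. Of the fewer genes tested without the lowest 50%, 8020 passed (2140 higher), so these counts have different totals. The correlation of the effects ran from -0.109 without wild-type replicate 2 to 0.0581 without heterozygous replicate 3 of experiment 2. Lists for both experiments went from 10 to 0 with an estimated correlation, fry or exact permutation, to 4 without the 3 arrays and to 5 to 12 with 1 array left out (5 without heterozygous and 6 without wild-type replicate 3 of experiment 1); between experiments from 16 to 0 with an estimated correlation, 34 with fry, 3 without the lowest 50% of genes (all higher) and 3 with quantile normalisation. For experiment 1 they went from 10 to 0 with an estimated correlation or fry and to 6 without the 3 arrays, for experiment 2 from 4 to 0, 0 and 1, and to 0 to 4 with 1 array left out (0 without wild-type replicate 1, 2 without wild-type replicate 3, 1 without any heterozygous replicate of that experiment), and for the difference from 5 to 0 and 0. Reversed values were Kmt2d, -0.23 by the mean of its probe sets, which averages 2 probe sets of opposite sign, and the glucocorticoid list, 0.0198 without the 3 arrays, whose cause was not tested. Of 556 values for the 20 genes and Kmt2d 535 kept their direction and side of the threshold and 20 passed it, 13 with array weights, 3 with list means as covariates and 4 with 1 array left out. Of 95 values for the 4 genes of experiment 1 60 kept both and 35 lost the threshold, with none reversed. A filter that removed a gene gave it no value. The replicate numbers do not pair the mice: deviations of same-numbered mice correlated at 0.22, -0.09 and -0.23 in experiment 1 and -0.21, -0.04 and -0.12 in experiment 2, and only replicate 1 of experiment 1 correlated best with its own number. With the replicate block 0 genes passed for both experiments, 1 for experiment 1, 0 for experiment 2, 0 for the difference, and 11 lists, while the difference between experiments could not be fitted with it. Signal over background limits dim genes, for which a change on the log2 scale is compressed.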

Other observations

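The genes named in the next paragraph, the comparison of septal markers between genotypes and the scaling of receptor genes were chosen after the results were seen. For the other tests in this part the predictions were written before the tests were run. Those on septal genes and on the difference between the experiments were set for patterns already seen in the results. Further genes among the 55 with an unadjusted p under 0.05 and the same sign in both experiments, none past the threshold over all genes, are given as values. The semaphorin gene Sema3e differed by 0.30 over both experiments, the ephrin receptor gene Epha7 by 0.30, the cadherin gene Cdh12 by 0.32 and the growth factor gene Fgf10 by 0.30, all higher in heterozygous mice. Pld4 was at -0.31, Arhgdib at -0.48 and the protease gene Ctss at -0.26, while Fcrls was at 0.40, and the microglia and macrophage list, which holds Ctss and Fcrls, did not pass (mean -0.034, 15 of 23 below 0; camera adjusted p = 0.116; adjusted p = 0.701 with an estimated correlation). Between the experiments, 45 of 51 small nucleolar RNAs passed, 19 higher and 26 lower in experiment 2, with a median absolute difference of 0.78 against 0.39 over all genes, a contrast that was not tested. The lower ones outnumbered the higher ones under each scaling, 30 to 11 with equal array medians and 32 to 12 with quantile normalisation. Of 291 microRNA genes 219 passed, 202 of them higher, and of 167 vomeronasal receptors 91 passed, 90 of them higher, both as deposited only, since other scalings were not run for these families.

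The genes Zic1, Zic4, Glp1r, Slc10a4, Ecel1, Ano2, Pld5 and Ctxn3, known from septum and other forebrain tissue near the hippocampus, were lower in heterozygous mice of both experiments, with a mean of -0.78 over the 8 genes (exact permutation p = 0.00143, the smallest possible, on genes chosen for this pattern), -0.97 in experiment 1 and -0.55 in experiment 2. Variants linked to the Kmt2d allele that act on neighbouring genes are argued against as the whole cause, since 0 of the 8 genes lie on chromosome 15. Where the genes lie cannot decide on linked variants that act on genes of other chromosomes. The male wild-type array is argued against too, since the mean with it was 1.06 times that without it (-0.73). Carry-over of septal tissue could be a source and stays open: all 11 measured of 13 other septal markers were lower over both experiments, by a mean of -0.25, or -0.35 in experiment 1 and -0.14 in experiment 2, where Crhr2 (0.13) and Lhx8 (0.06) were above 0 (exact permutation p = 0.00429; camera p = 3.24e-08; p = 0.000312 with an estimated correlation), among them Trpc4 (-0.06, at a mean of 9.76 log2 units), Zic2 (-0.53), Zic5 (-0.50) and the choline transporter gene Slc5a7 (-0.45). With group means removed, the 8 genes and these markers correlated at Pearson r = 0.492 over 13 arrays (permutation p = 0.0847) and Spearman rho = 0.489 (permutation p = 0.0924), r = 0.614 without the 2 arrays farthest from the median, 0.756 within experiment 1 (n = 7) and 0.274 within experiment 2 (n = 6), and the adjusted p was 0.0847 and 0.0924. An effect of genotype on these genes within the hippocampus was not tested and is a hypothesis that also remains.

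Most genes differed between the experiments, 15385 of 19938. Of 1027 olfactory receptor genes, which have no known role in hippocampus, 76.1% passed as deposited (782 genes, 779 of them higher) against 77.2% of all genes, which may point to the array run, labelling or hybridisation. Saline injections alone were expected to leave under 10% of the receptors past the threshold, and 50% or more was set as the share against them. The share as deposited passed that bound. However, the receptors were dim, at a median level of 4.42 log2 units against 7.54 over all genes, and their median difference was 0.29. With array medians made equal the share was 39.5% against 69.4% of all genes, and with quantile normalisation 31.6% against 63.8%. Both shares lay between those bounds and below the share of all genes, at median differences of 0.05 and 0.07. The receptors therefore decide neither on the array run nor on saline injections alone, because the bound was passed only as deposited. How much of the difference in other genes came from the injections cannot be told apart from the array run, because each experiment had only 1 condition.

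Other splits of the mice were set beside each count. For genotype over both experiments 36 of 100 splits within experiments gave at least the real 1046 genes at an unadjusted p under 0.05, the highest other 2890, so chance was not excluded, and for the difference of the effects 25 of 100 gave at least 1301, the highest other 3852. Such counts may reflect a structure of the samples other than genotype, which was not tested for these splits. For experiment 1, 2 of 35 splits gave at least 4 genes past the threshold, so chance was not excluded, and the highest other, with 62 genes, set wild-type replicates 1, 3 and 4 against the rest, which puts wild-type replicate 2 with the heterozygous mice. For experiment 2 the 10 splits are too few for a share under 0.05; 3 gave at least the real 2042 genes, the highest other 4329. For the lists, 9 of 100 splits gave at least 10 past the threshold with camera, the median being 5.5 and the highest other 16, so chance was not excluded and camera at its preset correlation called lists often on regrouped mice. For the difference between experiments the real split alone, 1 of 100, gave 15385 genes, the median being 0 and the highest other 13454, and chance was excluded.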
